A study of Mus musculus with 14 samples.

How the data were processed

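ATAC-seq was performed on 50000 cells per library and sequenced as paired 50 nt reads at a stated depth of 40000000 to 45000000, without saying whether reads or pairs, per the labels' protocols. Reads were aligned to mm10, and BWA, SAMtools and Picard are named without versions, per the submitters' processing notes. Peaks were called with MACS2 on each library separately, per the peak names in the deposited files; the version and settings are not given in the sources used here. Peak numbers within the lists skip values, so some called peaks are not in the deposited lists. Whether reads were shifted for the Tn5 insertion offset is not given in the sources used here. Each deposited peak has a position, a summit offset, a score, a fold enrichment (a ratio over background), and −log10 p-values and q-values, all of them the authors' own values. They were used only to describe, rank or filter peaks within a list. In every deposited list 100% of the fold values were whole multiples of a single step, within 0.02 of a step, and 0 fold values were out of order with q, so that ranking by fold and by q gave the same order.

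Groups, replicate numbers and treatments were taken from the titles and characteristics. The ZR_DMSO libraries carry a PBS vehicle label, against their titles, and the EV libraries differ from each other, with a DMSO vehicle label on replicate 1 and a PBS one on replicate 2. All 14 libraries were used. Peaks outside chromosomes 1 to 19, X and Y were left out of the comparisons. The lists hold no read counts, so depth per library is unknown and no counting interval can be given; with 2 libraries per group, the SD is itself imprecise.

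For each comparison the 4 lists were reduced to the length of the shortest by −log10 q (34989 peaks for ZR against EV, 12390 for ZR_GSK343 and for ZR_dmCitra against ZR_DMSO, 29432 for Citraconate_50K against DMSO_50K), overlapping peaks were merged, and a library counted as having a region where a peak overlapped it by at least 1 bp. Regions gained, lost and in all 4 lists were counted, with the same counts for the other 2 splits of the 4 libraries. Fusion-gained, fusion-lost and shared regions were fixed in the ZR and EV libraries and then looked up in every library at 12390 peaks. Peak numbers and these percentages were compared by two-sided exact permutation tests.

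Gene positions came from a RefSeq gene table of assembly GRCm38.p6, the same coordinates as mm10. It gives no strand, so transcription start sites were not known, and the planned promoter window was replaced by 1 kb either side of both ends of each gene. A gene counted as having a gene-end peak in a library where either window held one. The peaks of the 2 libraries behind a call need therefore not overlap. For Agt, Tubb3 and, in ZR_dmCitra, Gls2 the best peaks of the 2 libraries lay at opposite ends. Genes with a gene-end peak were tested for 16 gene lists written before the data were examined by Fisher's exact test, two-sided, against all protein-coding genes with a peak in the comparison, with Benjamini-Hochberg adjustment over 128 tests. The lists covered genes associated with the fusion, NF-kB targets, itaconate and citric acid cycle, NRF2 targets, interferon response, Polycomb, Hox, developmental transcription factors, neural stem, neuron, astrocyte, oligodendrocyte, cilia, microglia, mesenchymal and vascular, and housekeeping. Of the list members 1 had no match in the table and is not reported, and some results under the naming rule are not reported here. A further test, chosen after the data were seen, compared gained with lost regions assigned to the protein-coding gene with the nearest end within 100 kb, for all of them and for those away from gene ends. Overlaps between comparisons were tested by Fisher's exact test over 32 tests, including regions away from gene ends, the latter and the overlap of GSK343 with the second citraconate comparison having been added after the data were seen. Motif content was not analysed because no genome sequence was used here.

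The genes and regions named were set by a rule written before the data were examined: up to 4 gained and 4 lost members of each list by the poorer of their ranks, the 10 gained and 10 lost regions of best poorer rank with no overlapping peak in the deposited lists of the other group, and Acod1, Rela, Ezh2, Ccnd1 and L1cam throughout. The remaining lost neural stem genes and the genes behind the region balance were named or counted after their values were seen. Alternatives were lists as deposited, −log10 q of at least 5, ranking by fold, a peak covering at least 50% of a region, ZR in place of ZR_DMSO, windows of 500 bp and 2 kb, pairing by replicate number, and leaving out each library. On simulated lists with 500 gained and 500 lost regions per comparison, the calling recovered 100% of both with 0 false calls; the simulated regions met the calling rule by construction, so this checked the code and not the error rate under replicate noise. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.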

Results

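Open chromatin was mapped by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in mouse neural stem cells. Some of the cells carried the ZFTA-RELA fusion, which joins the zinc finger protein ZFTA to the NF-kB subunit RELA and is known as a driver of supratentorial ependymoma. The data were 14 peak lists, 1 per library, in 7 groups of 2 libraries. EV denotes empty-vector cells and ZR fusion cells. ZR_DMSO, ZR_GSK343 and ZR_dmCitra denote fusion cells whose titles name the vehicle DMSO, GSK343 (an inhibitor of the histone H3 lysine 27 methyltransferase EZH2, 10 µM for 96 h) or dmCitra, with citraconate at 10 mM in the treatment label. DMSO_50K and Citraconate_50K came from a second library series, in which the control libraries carried an empty-vector label and the citraconate libraries a fusion label, so that treatment and cell line label cannot be told apart there. The citraconate protocol names 24 h and 48 h without assigning either to a library. No label says that replicates were separate cultures, so the spread between them may be technical.

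The lists held between 12554 and 60472 peaks. The means were 39357.5 ± 6019.6 in EV, 44829 ± 199 in ZR, 16848.5 ± 6073 in ZR_DMSO, 38573.5 ± 26956 in ZR_GSK343, 45058 ± 1219 in ZR_dmCitra, 56621.5 ± 5445 in DMSO_50K and 30719 ± 1619 in Citraconate_50K (SD, n = 2 each). ZR_DMSO replicates 1 and 2 had 12554 and 21143 peaks with a median width of 226 and 186 bp, against 419 to 533 bp in the EV, ZR, ZR_dmCitra, DMSO_50K and Citraconate_50K libraries. ZR_GSK343 replicates 1 and 2 had 19513 and 57634 peaks. Read depth per library is unknown from the lists. Lists were therefore compared at equal length, keeping the peaks with the highest −log10 q of each. A region was called gained when both test libraries and neither control library had a peak there, and lost in the opposite case. A comparison of 2 libraries with 2 has 3 splits, so the smallest two-sided exact permutation p is 0.333 and no single value can pass 0.05.

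With all lists at 12390 peaks, replicates shared 0.649 to 0.716 of their covered bases (Jaccard index) in the EV, ZR, ZR_dmCitra, DMSO_50K and Citraconate_50K groups, but 0.448 in ZR_DMSO and 0.439 in ZR_GSK343. ZR_dmCitra libraries lay closest to ZR, with a mean index of 0.627 against 0.194 to ZR_DMSO. Equal peak number was not equal coverage. The 12390 peaks covered 3.69 and 3.88 Mb in ZR_DMSO, 13.0 and 12.4 Mb in ZR and 13.7 and 12.7 Mb in ZR_dmCitra. The short ZR_DMSO peaks thus keep its index with these groups low whatever their positions. DMSO_50K libraries, labelled empty vector, had a mean index of 0.485 with ZR and 0.337 with EV.

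**Figure D1:**
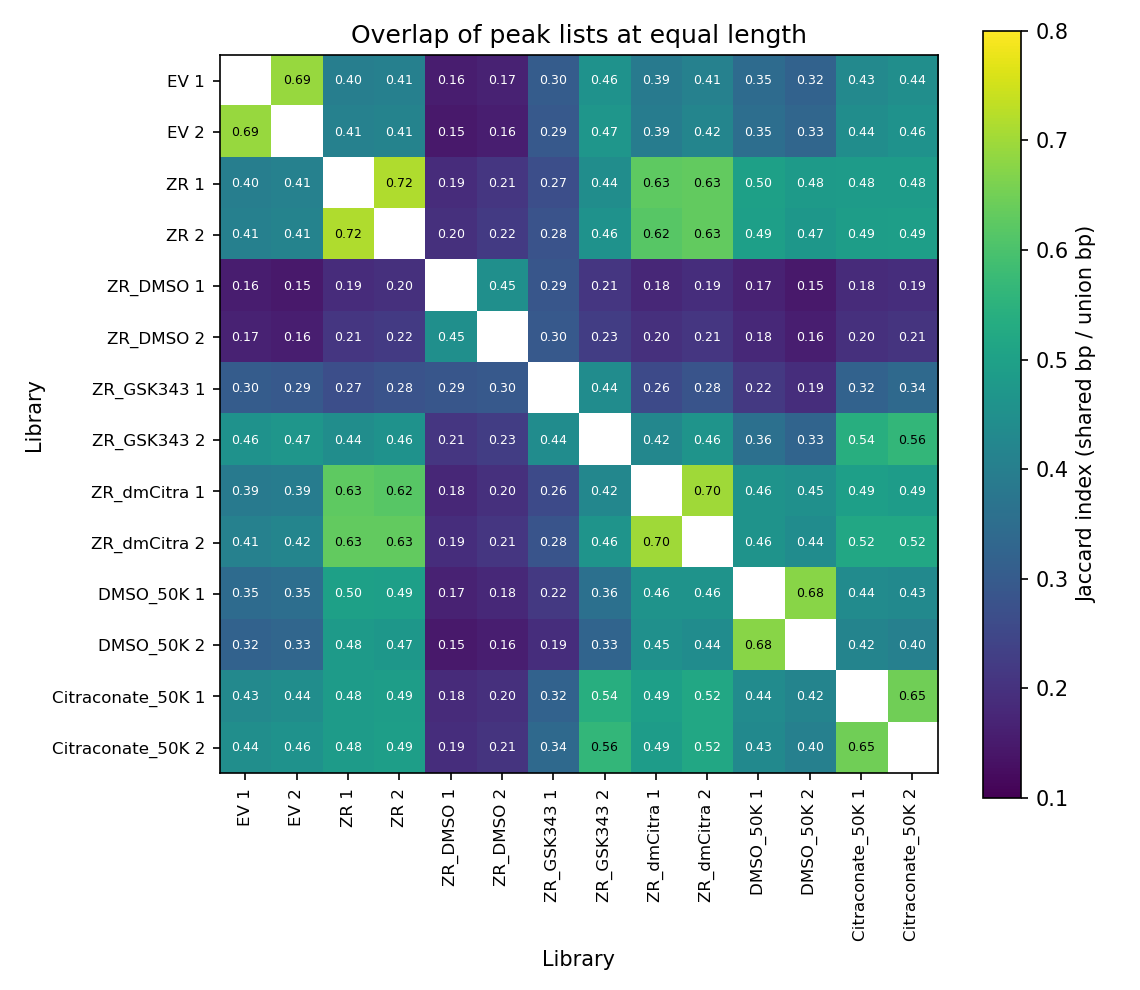
Jaccard index (shared bases over union bases) for each pair of the 14 libraries, with every list held at its 12390 best peaks; colour and printed numbers give the index. ZR and ZR_dmCitra form a block around 0.627, and ZR_DMSO libraries share at most 0.296 with a library of another group. The short ZR_DMSO peaks, which cover fewer bases, limit that index.

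The first comparison asked how chromatin differed between fusion and empty-vector cells. At equal list length 9 of 21 neural stem genes with a gene-end peak lost it in fusion cells, and 4 of 15 NF-kB target genes gained one. Sox2 and Sox1, which maintain neural progenitors, lost their gene-end peaks. The NF-kB targets Cxcl10, Cxcl1, Ccl2 and Tnf gained one. Over the genome 13270 regions were gained and 11682 lost among 60363, while the other splits of these 4 libraries gave 184 to 295 in either direction.

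The neural stem list had 21 genes with a peak within 1 kb of a gene end, and 9 of them lost it, which is 42.9% against 6.90% of all 11929 genes with a peak (Fisher's exact test, two-sided, Benjamini-Hochberg adjusted over 128 tests, adjusted p = 0.000599). Besides Sox2 and Sox1 these included Hopx, Dll1, Id3, Nr2e1, Hes5 and Nes; none of the list was gained. The Sox2 peak spanned chromosome 3, 34647940 to 34651175 in EV replicate 1 (mm10), ranked no lower than 2751 of 34989 in either EV list, and had no counterpart in either deposited ZR list. Sox1, Hopx and Nes were likewise without a gene-end peak in the deposited ZR lists. Dll1, Id3 and Hes5 had one in both, outside the equal-length lists. Id3 and Hes5 lie on chromosome 4, where 29.7% of regions were lost against 19.4% over all chromosomes. The losses at these genes can therefore not be told from a change along the chromosome. The neural stem test was not repeated without that chromosome. Assigned to the nearest gene end within 100 kb, 19 gained and 57 lost regions lay near neural stem genes (odds ratio 0.289, adjusted p = 4.31e-05 over 64 tests, Fisher's exact test chosen after the data were seen). Away from gene ends 19 were gained and 46 lost (Fisher's exact test, adjusted p = 0.00289). Slc1a3, a glial glutamate transporter gene, had 9 of the lost regions and no gained one. Gained regions lay near 9 of the listed genes and lost ones near 22. The test counts regions near the same gene as independent, so its p can overstate the evidence for the list.

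Of the 15 NF-kB target genes with a peak, 4 gained it (26.7% against 3.10%, Fisher's exact test, adjusted p = 0.0404) and Vcam1, an adhesion molecule gene, lost it. Both deposited ZR lists still had a gene-end peak at Vcam1, outside the equal-length lists. The Cxcl10 peak lay at chromosome 5, 92348849 to 92349175 in ZR replicate 1, with an authors' fold enrichment of 21.8 and 22.6 in the 2 ZR libraries. Of 14 developmental transcription factor genes with a peak, Six2, Twist2, Foxa1 and Tbx15 gained it (28.6%, Fisher's exact test, adjusted p = 0.0404) and Tbx2 lost it. The Six2 peak at chromosome 17, 85687984 to 85688944, was the strongest of these, with an authors' fold of 41.0 and 40.3. Tbx2 had a gene-end peak in both deposited ZR lists. Hoxa4 and Hoxa7 gained a peak among 3 Hox genes with one (Fisher's exact test, adjusted p = 0.0902). With a window of 2 kb the neural stem call held (Fisher's exact test, adjusted p = 0.0459), while NF-kB targets had an adjusted p of 0.340 and developmental factors 0.286; with 500 bp developmental factors had 0.167.

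No other list passed at 1 kb; at 500 bp the neuronal list did, with 4 of 8 lost (Fisher's exact test, adjusted p = 0.0441). Losses were found for 3 of 16 fusion-associated genes (Fgfr3, Cldn1 and Arl4d), 3 of 9 neuronal (Neurod1, Syp and Dlx2; Dlx1 was gained), 3 of 8 astrocytic (Gja1, Fgfr3 and Agt; Sparcl1 was gained), 2 of 7 mesenchymal and vascular (Kdr and Tagln), 1 of 6 oligodendrocytic (Olig2), 1 of 6 microglial (P2ry12) and 1 of 13 Polycomb genes (Kdm6b, a histone H3 lysine 27 demethylase). Acod1, which makes itaconate, gained a gene-end peak among 25 itaconate and citric acid cycle genes, although the deposited list of EV replicate 2 also had one. Irf7 was gained among 18 interferon response genes. Among 23 NRF2 target genes Gsta1 was gained and Keap1 lost. Fgfr3, Dlx2, Gja1 and Keap1 had a gene-end peak in both deposited ZR lists, and the other lost genes named here in neither. Irf7 had one in the deposited list of EV replicate 2. None of 12 ciliary and 22 housekeeping genes was called in either direction. Rela, Ezh2 and Ccnd1 had gene-end peaks in all 4 lists, and L1cam in none.

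**Figure D2:**
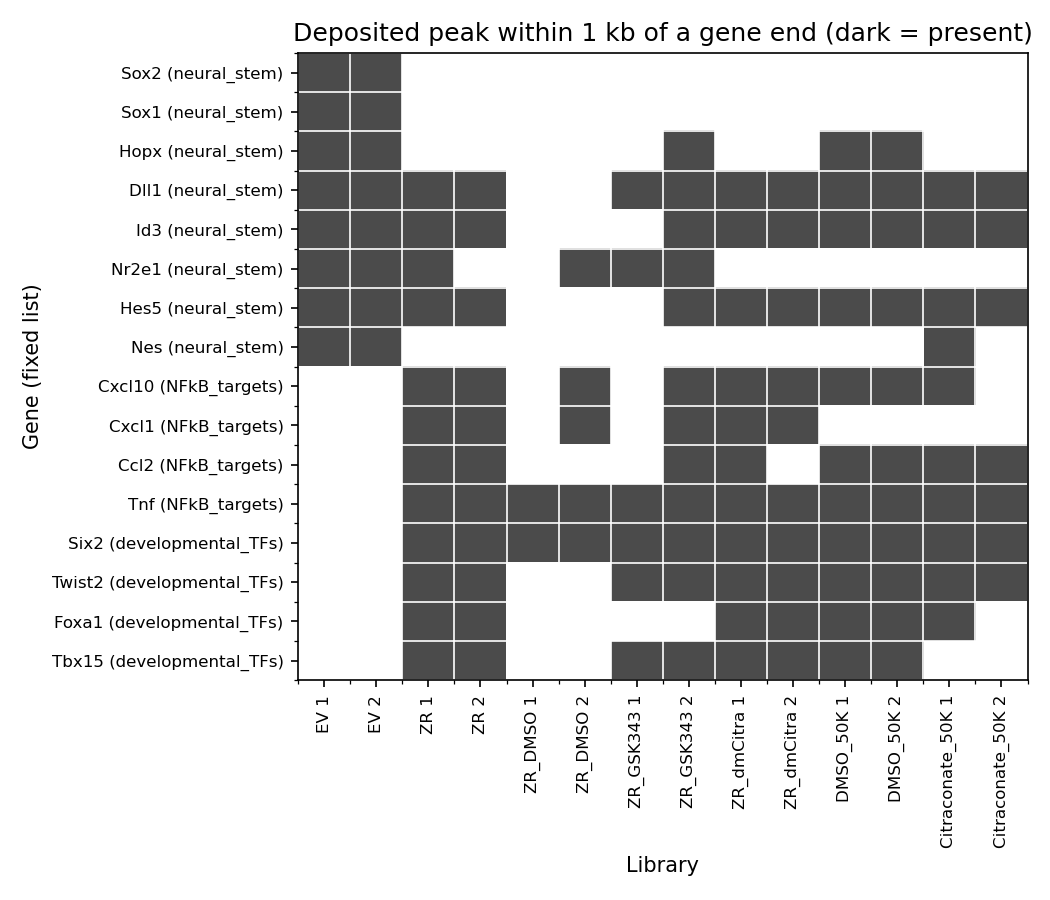
Presence (dark) or absence (light) of a deposited peak within 1 kb of a gene end for named neural stem genes lost and the NF-kB and developmental genes gained in ZR against EV; columns are the 14 libraries. Sox1 and Sox2 are dark in the 2 EV libraries only, and Six2 is dark in all libraries except EV.

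The best-ranked gained regions that overlapped no deposited EV peak lay inside Ptpre (chromosome 7, 135604540 to 135606102), inside Map2k6, a kinase upstream of p38, nearest to Pax9 within Slc25a21, inside Ifi209, within Cntnap4, near Bcas1, within Hs6st3, on chromosome 13 with no gene end within 100 kb, inside Kcnk2 and near Rxfp2. The best-ranked lost regions lay at Pou3f2, a neural POU factor gene (chromosome 4, 22486763 to 22490607), near Macrod2, at Gm41607, near Astn2, Tmtc2 and Lmo4, within Nkain3 and Negr1, near Gm52523 and at Frmd3. Only 4.49% of gained and 8.54% of lost regions lay within 1 kb of an end of a protein-coding gene, against 57.0% of the 14682 regions in all 4 lists. ZR lists were 1.14 times as long as EV lists (exact permutation p = 0.333). Chromosome 4 had 10.2% of its regions gained and 29.7% lost, against 22.0% and 19.4% over all chromosomes. The best-ranked lost regions at Pou3f2 and Frmd3, near Astn2 and within Nkain3 lay on it. Its 96 gene-end regions that every deposited list contains also ranked lower in ZR. Their median percentile, higher being stronger, was 75.2 and 72.9 in EV and 34.1 and 38.3 in ZR. Losses at single genes on chromosome 4 can therefore not be told from a change along the chromosome. Whether its DNA copy number differed between the cell lines was not tested. Without chromosome 4, 12970 regions were gained and 10811 lost.

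**Figure D3:**
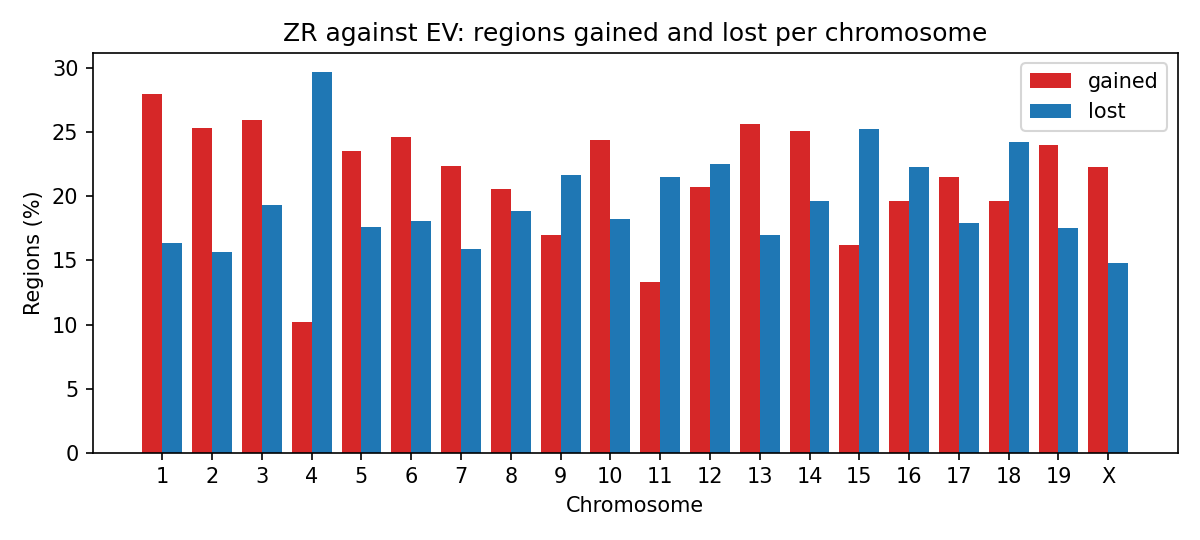
Percent of the regions on each chromosome that were gained (red) or lost (blue) in ZR against EV at equal list length; chromosome Y is not drawn. Chromosome 4 stands out with 29.7% lost and 10.2% gained.

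The second comparison asked what EZH2 inhibition did to open chromatin in fusion cells. At equal list length ZR_GSK343 libraries had gene-end peaks that ZR_DMSO libraries lacked, among them those of the NF-kB inhibitor Tnfaip3, of Nfkb1 and of the developmental factors Msx1, Foxf1 and Foxc1, and lacked peaks away from gene ends. All of these genes but Foxf1 also had the peak in both ZR and both EV lists at that length, and Nfkb1, Msx1 and Foxc1 had it in the deposited list of ZR_DMSO replicate 2. Regions gained numbered 2240 and regions lost 1656 of 21521, with 236 to 454 in the other splits. A peak was absent from both deposited ZR_DMSO lists at 1385 of the gained regions, and from both deposited ZR_GSK343 lists at 307 of the lost. Most losses were thus changes of rank among deposited peaks. Of the gained regions 77.6% lay at gene ends, against 3.74% of the lost. The regions gained with the fusion had a peak less often: 5.41% in ZR_GSK343 and 18.7% in ZR_DMSO, a difference of -13.3 percentage points ± 3.59 (SD, n = 2 each, exact permutation p = 0.333, the smallest possible). Regions shared by ZR and EV had a peak in 62.8% and 45.9%.

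A gene-end peak was gained at 1945 genes and lost at 37 of 9652, and no list stood apart from this general gain. Developmental factors had 5 of 9 gained (55.6% against 20.2%, Fisher's exact test, adjusted p = 0.323). Polycomb genes had 3 of 11 gained, namely Mtf2, Ezh1 and Phf19. Itaconate and citric acid cycle genes had 4 of 23 (Gls2, Ogdh, Suclg1 and Idh3b), NRF2 targets 3 of 19 (Gsr, Keap1 and Ephx1), NF-kB targets 2 of 12, interferon response genes 2 of 15 (Ifit2 and Irf1; Mx2, annotated as a transcribed pseudogene and so outside the test, was lost), neural stem genes 2 of 12 (Msi2 and Id1) and housekeeping genes 2 of 19 (Ppia and Tfrc). Single gains were Cachd1 of 12 fusion-associated, Dlx1 of 5 neuronal, Aldoc of 3 astrocytic, Foxj1 of 7 ciliary and Spi1 of 4 microglial genes. None was gained of 2 Hox, 2 oligodendrocytic and 4 mesenchymal and vascular genes. Mx2 kept a gene-end peak in both deposited ZR_GSK343 lists. Ezh2 had a gene-end peak in all 4 lists, Rela in both ZR_GSK343 lists and ZR_DMSO replicate 1, Ccnd1 in ZR_GSK343 replicate 2, and Acod1 and L1cam in none.

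The best-ranked gained regions absent from the deposited ZR_DMSO lists lay at the ends of Agps (chromosome 2, 75831851 to 75832703), Dip2a, Tm2d3, Sik1, Sft2d2 and Uimc1, within 1 kb of those of Tubgcp3, Map4k3 and Ppip5k1, and within Pcmt1 near Nup43. The best-ranked lost regions were short and mostly intergenic, such as chromosome 16, 91534590 to 91534701 near Ifngr2, and lay also near Ndufb3, Chst2, Pigk, Mrln, Xcr1, Peg10, Gm13285, Gsdma2 and, on chromosome Y, LOC665918. The median width of lost regions was 278.5 bp, against 858 bp for gained ones. As deposited, the lists gave 4991 gained and 477 lost regions, and the difference in fusion-gained regions turned to 7.49 points ± 37.6 (SD, n = 2 each, exact permutation p = 1), with ZR_GSK343 replicates 1 and 2 at 7.58% and 58.3% and ZR_DMSO at 17.5% and 33.4%. With a peak required over 50% of a region 4328 were gained, and with ZR as control 4472 were lost. Peak number was 2.29 times that of ZR_DMSO (exact permutation p = 0.667), 1.16 times without ZR_GSK343 replicate 2 and 3.42 times without replicate 1, and gained regions numbered 4097 without ZR_GSK343 replicate 1 and 4630 without replicate 2. Lost regions numbered 2538 without ZR_GSK343 replicate 2, and 3844 and 3869 without ZR_DMSO replicates 1 and 2.

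**Figure D4:**
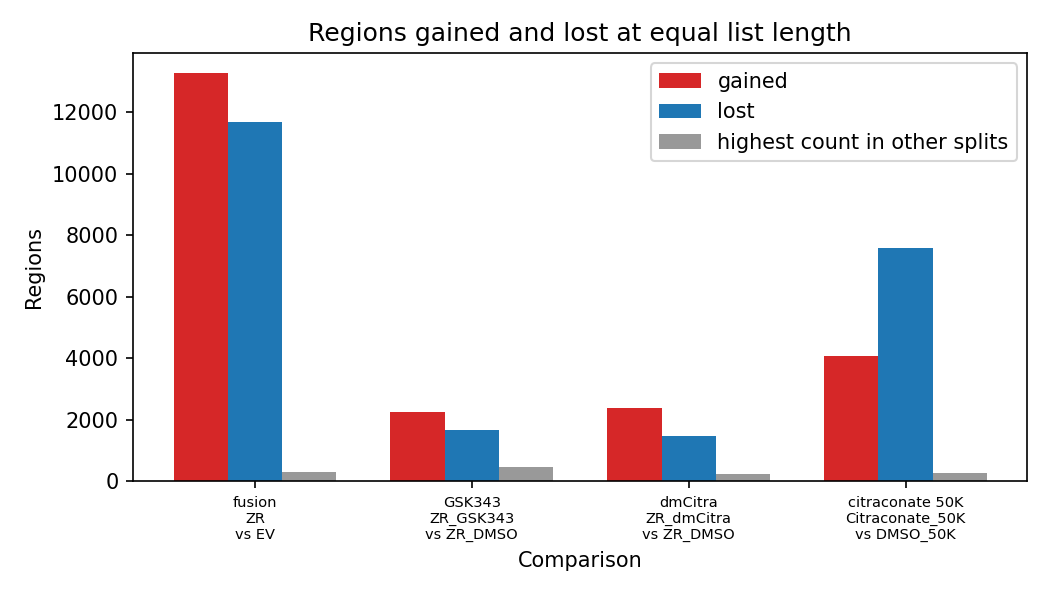
Regions gained (red) and lost (blue) in each comparison at equal list length, beside the highest count in the other splits of the same 4 libraries (grey). The fusion comparison has 13270 gained and 11682 lost regions, and every real count exceeds the grey bar beside it.

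The third comparison asked what citraconate, an inhibitor of the itaconate-producing enzyme ACOD1, did in fusion cells of the first series. ZR_dmCitra libraries had peaks at the ends of Tnfaip3, Nfkb1 and Cxcl1, of Foxc1 and Msx1, and of the X-linked demethylase gene Kdm6a that ZR_DMSO libraries did not have at equal length. Both ZR lists had these peaks too, except that of Cxcl1, which was in ZR replicate 1. Regions gained numbered 2378 and regions lost 1473 of 19790, with 145 to 232 in the other splits. A peak was absent from both deposited ZR_DMSO lists at 1439 of the gained regions, and from both deposited ZR_dmCitra lists at 207 of the lost. Most losses were thus changes of rank among deposited peaks. Fusion-gained regions had a peak in 26.6% in ZR_dmCitra, 18.7% in ZR_DMSO and 26.2% and 25.8% in the 2 ZR libraries. The difference from ZR_DMSO was 7.86 points ± 2.26 (SD, n = 2 each, exact permutation p = 0.333), and regions shared by ZR and EV differed by 10.5 points.

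Gene-end peaks were gained at 943 and lost at 109 of 7859 genes, and no list passed. Gained were 3 of 7 developmental factors (Fisher's exact test, adjusted p = 0.591), 3 of 12 NF-kB targets, 3 of 18 itaconate and citric acid cycle genes (Suclg1, Ogdh and Gls2, with Sdhd lost), 3 of 18 housekeeping genes (Hprt, Ppia and Vcp), 1 of 18 NRF2 targets (Gsr), 1 of 8 Polycomb genes (Kdm6a, with Suz12 lost) and 1 of 7 ciliary genes (Dnaic1). Of 12 interferon response genes Psmb9 and Tap1 were lost (Fisher's exact test, adjusted p = 0.294). Both calls rest on the same peaks, and the best ones of the 2 ZR_DMSO libraries there did not overlap. Sdhd, Suz12, Psmb9 and Tap1 kept a gene-end peak in both deposited ZR_dmCitra lists. None was called among 9 fusion-associated, 8 neural stem, 1 neuronal, 1 astrocytic, 1 oligodendrocytic, 3 microglial and 3 mesenchymal and vascular genes, and no Hox gene had a peak. Ezh2 had a gene-end peak in all 4 lists, Rela in ZR_DMSO replicate 1, and Acod1, Ccnd1 and L1cam in none at this length.

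The best-ranked gained regions lay within Fras1 (chromosome 5, 96619770 to 96621077), at Naa11, Nop10, Clasp1, Prkx and Gm3776, near Tmprss11f and Adamts16, and on chromosomes 3 and 1 with no gene end within 100 kb. The best-ranked lost ones were short, from chromosome 4, 70378119 to 70378255 within Cdk5rap2 to others near Pcnx2, Ifngr2, Il31ra, Zfp746, Oasl1, Chst2 and Gnb1l and, without a near gene, on chromosomes 18 and 1. ZR_DMSO had 1.98% and 1.65% of its 12390 best peaks on chromosome Y, and ZR_dmCitra 0.0161% and 0.00807%. Against ZR in place of ZR_DMSO there were 2964 gained and 3274 lost regions, and as deposited 19807 and 361. With a peak required over 50% of a region 9740 were gained. The ZR_dmCitra lists were 2.67 times as long as ZR_DMSO (exact permutation p = 0.333), and without ZR_DMSO replicate 2 the counts were 3955 and 4115, without replicate 1 3507 were lost.

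The fourth comparison set Citraconate_50K against DMSO_50K. Regions near targets of NRF2, the transcription factor of the antioxidant response, were gained more often than lost. Those near mesenchymal and vascular genes were lost more often than gained. The gene-end peak of Acod1 was absent in Citraconate_50K, but both deposited ZR_dmCitra lists had one. Regions gained numbered 4086 and regions lost 7601 of 45142, with 214 to 248 in the other splits. Of the gained regions 860 had no peak in either deposited DMSO_50K list. Of the lost ones 7427 had none in either deposited Citraconate_50K list. Most gains were thus changes of rank among deposited peaks. Of 118 regions near NRF2 targets 20 were gained and 6 lost (odds ratio 4.77, adjusted p = 0.0130, Fisher's exact test over 64 tests chosen after the data were seen). Of 53 regions near mesenchymal and vascular genes 1 was gained and 17 lost (odds ratio 0.0836, Fisher's exact test, adjusted p = 0.0269), against 3561 and 5061 near other genes; away from gene ends the counts were 1 and 16, which did not pass (adjusted p = 0.125). Neuronal genes had 3 gained and 17 lost of 59 (Fisher's exact test, adjusted p = 0.258). Gained regions lay at gene ends in 23.6% and lost ones in 2.80%, and away from gene ends 16 regions near NRF2 targets were gained and 6 lost (odds ratio 5.02, adjusted p = 0.0128, Fisher's exact test). Housekeeping genes had 4 gained and 1 lost, and interferon response genes 3 and 0, which did not pass. All of these tests count regions near the same gene as independent, so their p-values can overstate the evidence for a list.

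The NRF2 target with the most gained regions was Srxn1, which encodes sulfiredoxin, with 6; Gclm, for a glutathione synthesis subunit, had 2, and Hmox1 and Txnrd1, for heme oxygenase and thioredoxin reductase, 1 each. In all 13 of the listed genes had a gained and 4 a lost region, Me1 having 2 lost. At gene ends 3 of 22 NRF2 targets were gained (Gsta1, Keap1 and Cbr3), which did not pass. Keap1 and Cbr3 had a gene-end peak in both deposited DMSO_50K lists, and Gsta1 in that of replicate 2. Dcn, for the matrix proteoglycan decorin, had 6 of the lost regions, Acta2 3 and Col3a1 2. The Dcn gene-end peak at chromosome 10, 97478158 to 97480474 was in both deposited DMSO_50K lists and in neither Citraconate_50K list. The Acod1 peak lay at chromosome 14, 103046442 to 103047823, with an authors' fold of 40.2 and 47.2 in the DMSO_50K libraries. It was also in neither deposited Citraconate_50K list. In the first series both deposited ZR_dmCitra lists and that of ZR_DMSO replicate 2 had a gene-end peak at Acod1.

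Gene ends were gained at 852 and lost at 169 of 11366 genes, and no list passed by that measure. Other gains were 2 of 13 Polycomb genes (Ezh1 and Phf1), 2 of 6 neuronal (Tubb3 and Syn1, with Snap25 lost), 1 of 14 fusion-associated (Arl4d), 1 of 18 NF-kB (Il6), 1 of 24 itaconate and citric acid cycle (Idh3b, with Acod1 lost), 1 of 15 neural stem (Dll1), 1 of 5 oligodendrocytic (Cnp, with Mobp lost) and 1 of 22 housekeeping genes (Rpl4). Each of these gained genes but Cnp had a gene-end peak in both deposited DMSO_50K lists, and Cnp in 1. Tmem212 was lost among 10 ciliary genes and Dcn among 6 mesenchymal and vascular genes (Fisher's exact test, adjusted p = 0.786). None was called of 19 interferon response, 5 Hox, 13 developmental, 5 astrocytic and 6 microglial genes. Ezh2 and Ccnd1 had gene-end peaks in all 4 lists, Rela in all but DMSO_50K replicate 1, and L1cam in none.

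Fusion-gained regions had a peak in 13.6% in Citraconate_50K and 25.2% in DMSO_50K, a difference of -11.6 points ± 1.26 (SD, n = 2 each, exact permutation p = 0.333), while regions shared by ZR and EV had one in 65.4% and 51.9%. The best-ranked lost regions included a pair within Nrxn3, a gene of a synaptic adhesion protein (the best at chromosome 12, 89441693 to 89443495), and others near Rttn, Edn3 and Macc1, with 4 more far from any gene end. The best-ranked gained ones were short, on chromosome 14 (86198991 to 86199142), near Cd209a, Litaf, Efcab11, Zfp746, Ank1 and Aasdhppt, within Kcnip1, and on chromosomes 18 and 16. The lists were 0.543 times as long as those of DMSO_50K (exact permutation p = 0.333), and as deposited 945 regions were gained and 20891 lost. With a peak required over 50% of a region 11475 were lost. Without Citraconate_50K replicate 1 or 2 the gained regions numbered 8668 or 8842.

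**Figure D5:**
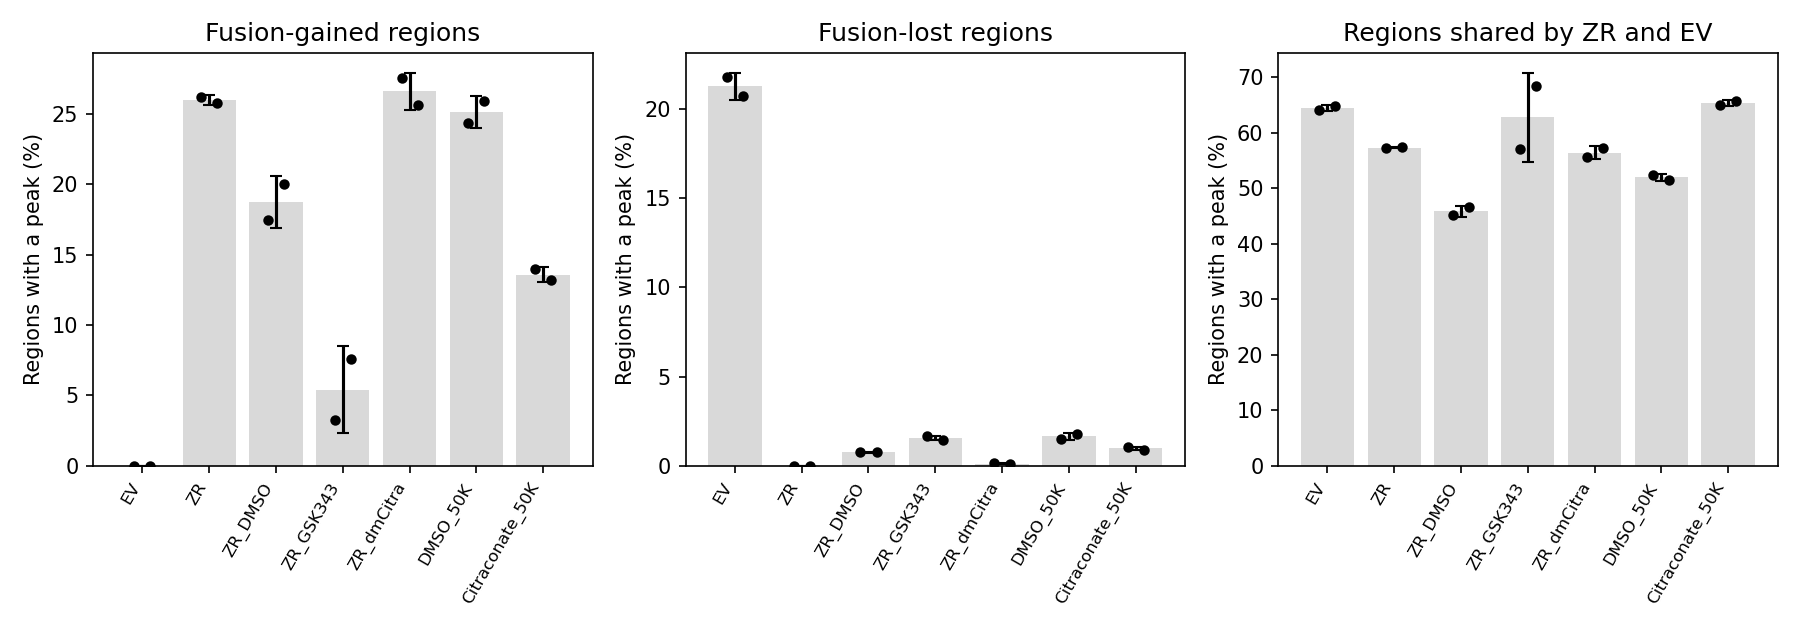
Percent of fusion-gained, fusion-lost and shared regions with a peak in each group, every list held at 12390 peaks; points are the 2 libraries, bars their mean and error bars the SD. Fusion-gained regions average 5.41% in ZR_GSK343 and 13.6% in Citraconate_50K, against 26.6% in ZR_dmCitra.

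Comparisons without shared libraries were then overlaid at 12390 peaks each, except where given otherwise. GSK343 and the second citraconate comparison had 570 lost regions in common where independent calls would give 128 (odds ratio 11.9), and 689 gained where they would give 259 (odds ratio 5.23); away from gene ends the odds ratios were 4.48 and 6.22. The 2 citraconate comparisons had 415 gained regions in common against 210 for independent calls and 235 lost against 77.9 (odds ratios 2.74 and 4.74). Regions lost in the first and gained in the second were also more than independent calls would give, 143 against 82.6 (odds ratio 2.03), and those gained in the first and lost in the second were fewer, 115 against 198. With ZR as the control of the first and 29432 peaks per list, 689 lost regions were common against 195 (odds ratio 6.62), and regions lost in the first and gained in the second were then fewer than for independent calls, 98 against 139 (odds ratio 0.675). GSK343 and ZR_dmCitra against ZR had 168 lost regions in common against 78.4 (odds ratio 2.69) and 80 gained against 47.2. All of these had an adjusted p below the threshold by Fisher's exact test, the largest being 0.000137 over 32 tests, but regions are not replicates and the tests describe these libraries.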

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

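The tests of how many fusion-gained regions are kept and of the DMSO_50K label were chosen after related values had been seen; the test on the ZR_DMSO libraries was set beforehand.

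At equal list length fusion-gained regions had a peak 7.86 percentage points more often in ZR_dmCitra than in ZR_DMSO, and the Citraconate_50K difference from DMSO_50K was -11.6 points, with every treated library on the stated side of both its controls. After subtracting the difference over shared regions the first was -2.69, the sign of the second series, so opposite directions depend on that choice. The interaction of 19.4 points had an exact permutation p of 0.0556, the smallest that 36 arrangements allow. Peak number ratios went the same opposite ways, 2.67 in the first series and 0.543 in the second. A candidate explanation for the first is ZR_DMSO libraries too weak to show regions that are open in ZR. Of the regions gained in ZR_dmCitra 51.4% had a peak in both ZR libraries at equal length, between the bounds set for and against. Weak controls and a treatment difference can therefore not be told apart by this share. In both deposited ZR lists, for which no bound was set, 98.5% had a peak. For GSK343 the share at equal length was 29.0%, below the 50% set as the bound. Most of these regions were thus not among the 12390 best peaks of both ZR libraries. However, 97.4% had a peak in both deposited ZR lists, and 1385 of the 2240 had none in either deposited ZR_DMSO list. A rank limit in ZR cannot tell why ZR_DMSO lacked them, so weak controls stay open.

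The lower share of fusion-gained regions with GSK343 and in Citraconate_50K might come from weaker libraries that drop their weaker peaks first. Fusion-gained regions away from gene ends (12674) were therefore set against shared regions away from gene ends (6316) of the same ZR rank. The share of fusion-gained regions kept, relative to shared ones, was at most 0.318 with GSK343 and at most 0.745 with citraconate over the 4 pairings of a treated with a control library. The ZR_DMSO libraries, set against ZR_dmCitra in the same way, gave 0.682 to 0.852, so a ratio of that size may come with weak libraries. The GSK343 values lie below that range, which argues against a loss of weak peaks of the size seen in ZR_DMSO. That range comes from a single pair of groups whose own difference is unresolved, so a larger technical loss in ZR_GSK343 stays open. For citraconate a loss of weak peaks stays open. A treatment effect on fusion-gained regions stays open as a hypothesis that was not tested further. The cell line labels stay open for the second series. So does, for GSK343, the reversed difference in lists as deposited (7.49 points ± 37.6, SD), which replicate 2 alone carries.

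DMSO_50K libraries, labelled empty vector, resembled ZR libraries. At their own list length they had a peak at 80.2% and 83.3% of fusion-gained and 22.1% and 22.6% of fusion-lost regions, and no gene-end peak at Sox1 or Sox2. Such values would be seen if the cell line label were wrong and the cells carried the fusion. They rest on the same lists as the similarity to ZR, so they are not separate evidence for it. The share of peaks on chromosome 4 was 5.85% and 5.89% there, 6.56% and 6.54% in Citraconate_50K, 6.22% and 6.35% in EV and 2.76% and 2.72% in ZR. It lay near EV and apart from ZR in both groups of the second series. For DMSO_50K this goes with the empty-vector label. The fusion-labelled Citraconate_50K libraries show it too, so it cannot decide about the label. Empty-vector cells that left the neural stem cell state without the fusion were not tested.

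Peaks on unplaced contigs, which no comparison used, were 1.64 times as many in ZR_GSK343 as in ZR_DMSO and 1.34 times as many in Citraconate_50K as in DMSO_50K, each treated library above both controls. As a share of the list they were 1.40% and 0.736% in ZR_GSK343 against 1.31% and 1.24% in ZR_DMSO, with no common direction, and 0.508% and 0.480% in Citraconate_50K against 0.191% and 0.208% in DMSO_50K.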

How the results depend on the processing

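ZR as control of Citraconate_50K, ZR_dmCitra in place of ZR_DMSO, leaving out chromosome 4 and using only regions away from gene ends were chosen after the data were seen. Of 122 alternative values 85 stayed within the replicate spread or within 1.5 times the count or on the same side of the threshold, 30 moved, 4 lost a call, 1 gained a call (neuronal losses at 500 bp) and 2 reversed. All fusion counts stayed within 1.5 times. Ranking by fold moved nothing, by construction, and so tests nothing. As deposited, gained and lost regions were 4991 and 477 (GSK343), 19807 and 361 (dmCitra), and 945 and 20891 (citraconate 50K), which follows the list lengths. With −log10 q of at least 5 and lists likewise not equalised they were 4723 and 419, 20006 and 308, and 709 and 21673. With a peak required over at least 50% of a region, 4328 were gained with GSK343, 9740 with dmCitra, and 11475 lost in citraconate 50K. With ZR as control 4472 regions were lost with GSK343 and 3274 with dmCitra. Leaving out single libraries, so that fewer lists must agree, gave 3158 to 4630 gained and 2075 to 3869 lost (GSK343), 3300 to 3955 and 1670 to 4115 (dmCitra), and 4870 to 8842 gained (citraconate 50K). The difference in fusion-gained regions reversed for GSK343 in lists as deposited (7.49 points ± 37.6, SD; only ZR_GSK343 replicate 2, the longest of those 4 lists, lay above ZR_DMSO), and was -30.3 after subtracting that of shared regions and -21.2 against ZR_dmCitra. For dmCitra it was 61.2 as deposited and reversed to -2.69 after subtracting shared regions, which differed more. NF-kB targets had 16.7% gained at 2 kb, and developmental factors 23.1% at 500 bp and 18.8% at 2 kb, no longer past the threshold; nor was the balance near mesenchymal and vascular genes away from gene ends (odds ratio 0.117). Pairing by replicate number (block) gave peak number ratios of 1.15, 2.14, 2.87 and 0.546 in the order of the comparisons, with a smallest exact sign-flip p of 0.5; the numbers are not stated to pair cultures. Motif tests were not run. Unknown depth limits every count here: a missing peak is not evidence of closed chromatin.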

Other observations

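The values in this part were chosen after the data were seen. At equal list length no treated group had as many neural stem genes with a peak as EV. At 12390 peaks per list, 17 and 13 of the 24 neural stem genes had a gene-end peak in EV replicates 1 and 2, and 5 to 9 in each of the other 12 libraries. Olig2, which marks the oligodendrocyte lineage, had a deposited gene-end peak in the EV libraries only, like Sox1 and Sox2. In the deposited list of ZR_GSK343 replicate 2, the longest of its group, 20 of the 24 genes had a peak, Hopx among them, against 21 and 22 in EV. Regions lost with the fusion had a peak in 1.65% and 1.46% in ZR_GSK343, 0.128% and 0.0856% in ZR_dmCitra, 1.04% and 0.899% in Citraconate_50K and 1.52% and 1.78% in DMSO_50K, and in 0.745% and 0.779% in ZR_DMSO. These regions were defined by their presence in EV and absence in ZR.

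Developmental transcription factor genes had the most gene-end peaks at this length in ZR_GSK343, 8 of 52 in each replicate. There were 2 in each ZR_DMSO library and 5 and 6 in ZR, but 6 and 7 in ZR_dmCitra and 7 and 6 in Citraconate_50K. Among Polycomb genes the counts were 10 and 11 of 13 in ZR_GSK343, 6 in each ZR_DMSO library, 7 in each ZR library and 10 in each EV library. Housekeeping genes went the same way, with 13 and 18 of 24 in ZR_GSK343 and 8 and 13 in ZR_DMSO, and gene-end peaks made up 56.7% and 64.1% of the ZR_GSK343 lists at this length and 39.0% and 39.9% of the ZR_DMSO lists.

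Chromosome 4 held a smaller share of peaks in ZR than in EV. It had 6.22% and 6.35% of the 12390 best peaks in EV and 2.76% and 2.72% in ZR, with 1.88% to 4.19% in the other fusion libraries of that series and 5.85% to 6.56% in the second series. Over 3931 gene-end regions that all 14 deposited lists contain, the median percentile of the 96 on chromosome 4, with 100 the strongest, was 75.2 and 72.9 in EV, 34.1 and 38.3 in ZR and 75.9 to 82.9 in the second series. These regions had to pass in the shortest lists too, which selects strong ones. On chromosome X the 71 such regions had a median percentile of at most 15.4 in the ZR_GSK343 libraries and of 42.2 and 52.5 in ZR_DMSO. It was also low in the second series, at 23.6 and 20.2 in Citraconate_50K and 31.4 and 30.2 in DMSO_50K. In EV, ZR and ZR_dmCitra it was 43.1 to 54.7. Whether the DNA copy number of these chromosomes differed between libraries was not tested.

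The same short regions recurred in different comparisons. A region on chromosome 18 (14103260 to 14103408) and one near Zfp746 on chromosome 6 (48121223 to 48121393) were among the best-ranked lost regions of ZR_dmCitra, and overlapping regions were among the best-ranked gained ones of Citraconate_50K. Regions on chromosome Y were lost in 38.7% of cases in ZR_dmCitra and gained in 41.8% in Citraconate_50K. Of the regions lost in ZR_dmCitra, 78.8% had no peak in either ZR library at equal length, and their median width was 317 bp against 1267 bp for regions in all 4 lists.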
